A study of Mus musculus with 32 samples.

How the data were processed

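PolyA RNA-seq was measured in dorsal hippocampus and cerebellar vermis of 16 C57BL/6J mice, which gave 32 libraries in 8 groups of 4 (WT or ACSS2 KO, prenatal ethanol or saline, by tissue), each with 2 females and 2 males. Per the labels' protocols, dams spent 5 nights with a stud, received 1 intraperitoneal injection a day of 3 g per kg ethanol (20% by volume) or saline until birth, and offspring were weaned at postnatal day 21 and killed by cervical dislocation at day 40 to 50. Libraries were made from 10 ng of RNA, and the labels give 1 sequencing batch. Time of day at death, litter, cage and library preparation batch are not given.

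The deposited gene table holds raw counts per gene for 56415 genes, and the deposited transcript table holds raw counts per transcript model, in which a read counts for every model it overlaps. Per the submitters' processing notes, bcl2fastq, cutadapt 5.0, STAR 2.7.10a, featureCounts 2.0.6 and DESeq2 were used with GRCm39, and the strand setting is not given. In the counts the mates of a pair were counted separately, since most low counts were even (83.9% in ethanol-exposed WT hippocampus F3, for example), and reads shared by genes were counted for each of them, since mt-Atp6 (mean 411832 counts) and its nuclear copy Atp6-ps (412035) had nearly the same counts. Calls of paralogs and pseudogenes are therefore not independent, and reads of an overlapping or antisense gene would add to Acss2. All coordinates are those of the deposited tables and give the first listed exon. Tables without annotation, which hold the same genes and others without a symbol, were not used here.

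Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1, and figures were drawn in Python 3.11.15 with matplotlib 3.10.9. The 16 libraries of each tissue were fitted together. Genes were kept by filterByExpr with the groups, scaled by TMM, and tested with robust quasi-likelihood F-tests with sex as a covariate. The Benjamini-Hochberg threshold was 0.05 over the genes tested (23394 in hippocampus, 22441 in vermis). The comparisons, 5 per tissue, were ethanol against saline within WT and within KO, KO against WT within saline and within ethanol, and the interaction. All 4 groups share one estimate of the spread, and comparisons that share a group are not independent. The difference of the exposure effect between tissues was tested on 24458 genes with mouse as a block, and that between sexes in models with a term for each sex and group. Acss2 was tested by exact permutation of log2 CPM of 8 KO against 8 WT libraries, and the genotype calls near Acss2 by Fisher's exact test within 10 Mb. Log2 CPM used a prior count of 2.

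A set of 43 gene lists was tested with camera in limma at a correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists, comparisons, rule for named genes and first set of alternative settings were chosen before the data were examined. The rule named, per comparison, up to 12 higher and 12 lower genes with the smallest p among those that passed with a mean of at least 1 CPM and no predicted name, or the 5 genes with the smallest p where fewer than 5 passed, then Acss2 and up to 4 members of each list described. The lists described were picked after their values were seen from those that passed, which were 19, 15, 15, 8 and 14 in hippocampus and 4, 22, 10, 19 and 14 in vermis, in the order of the comparisons. They include each list that also passed with an estimated correlation, and the choroid plexus and ependyma lists of exposure in WT hippocampus, which did not pass. Not every gene that the rule named is printed.

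A gene at 1 CPM has about 23.1 counts in the shallowest library and 96.7 in the deepest, and a 0 was taken to allow up to 3. Shares of counts in single libraries carry 95% Wilson intervals of counting error only. Simulations for the fit and camera had 100 genes changed by 1.5-fold, 100 by 2-fold and 40 shifted by log2 0.5 in WT. Recovery by fold was 59% and 91% in hippocampus (6 false of 177 calls) and 54% and 82% in vermis (3 of 156). For the interaction it was 35% and 74% (9 of 124) and 23% and 64% (9 of 103). KO, unchanged, gave 0 calls. Real KO libraries split otherwise gave up to 28 and 2589, so error rates may be higher. The 48 library pairs within groups, checked for copies, had a chi-square per degree of freedom of at least 9.05.

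The alternative settings chosen before were DESeq2 1.42.0, RLE scaling, no low-count filter, no sex term, the replicate label as a block, only the groups compared, sex by group cells, an estimated correlation and fry for the lists, genes of at least 10 CPM for the correlations, windows of 5 and 20 Mb, and each library left out in turn. Alternatives added after seeing the data were an offset for transcript length (lowess span of 0.3), protein-coding genes only, marker levels of neighbouring tissue as a covariate, and leaving out the pair of libraries farthest out on the first and on the third principal components. For the length test, the definition of length, the match of genes (within 10% of the length, 20 genes per member) and the bound were revised after results had been seen. On simulated slopes with length the offset left 0 calls where 658 (hippocampus) and 443 (vermis) were made without it. Bent trends, as in vermis, were not tested. Other splits of the libraries were fitted in full where 35 exist, and 75 were drawn for the interactions and 10 for the tissue tests, numbers set by computing time after larger draws had been seen. No per-sample column of the tables used was left out.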

Results

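Gene-level read counts were analysed from 32 polyA RNA-seq libraries of 16 C57BL/6J mice, each of which gave 1 library of the dorsal hippocampus and 1 of the cerebellar vermis. The mice were wild-type (WT) or knockouts (KO) of Acss2, which encodes the enzyme that makes acetyl-CoA from acetate. Their dams had received daily injections of ethanol (3 g per kg, cPAE) or saline (cPSE) until birth, and the offspring were killed at postnatal day 40 to 50. Each of the 8 groups held 4 libraries, from 2 females (F1, F3) and 2 males (M1, M3). Total counts ran from 54092519 to 96664509 per hippocampal library and from 23085928 to 73803508 per vermis library. Markers of Purkinje neurons, the output cells of the cerebellar cortex, averaged 6.82 to 8.17 log2 CPM (CPM, counts scaled to the total of the library) in the vermis libraries and 3.80 to 5.55 in the hippocampal ones. The sex of all 32 libraries matched its label.

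Acss2 (ENSMUSG00000027605, chromosome 2, GRCm39, forward strand, first exon 155359868 to 155360204) was lower in every KO library than in every WT library of the same tissue. In the hippocampus it measured 12.0 ± 1.00 CPM (SD, n = 8) in KO and 55.7 ± 4.19 CPM in WT, and in the vermis 16.7 ± 3.45 and 61.5 ± 4.76 CPM. The 2-sided exact permutation test over 12870 splits gave p = 0.000155 in each tissue, the smallest it can give, with log2 differences of -2.21 and -1.90. Acss2-206 (first exon 155391141 to 155391202) had 287 to 609 counts in the WT libraries and 0 in 8 of 8 KO vermis and 7 of 8 KO hippocampal libraries, where a count of 0 allows up to 3 counts. Acss2-201 stood at 19.6% of WT in KO vermis and 15.5% in KO hippocampus. Its counts include shared reads, so intact transcript was not measured. The 2 models that start nearest the 3′ end stood at 98.6% and 91.2% of WT in vermis and 140% and 136% in hippocampus. In the 10 Mb on either side of Acss2, 14 of 289 other tested genes passed the genotype test of saline-exposed vermis (4.84%) against 1087 of 22151 elsewhere (4.91%), with an odds ratio of 0.987 (Fisher's exact p = 1).

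**Figure D1:**
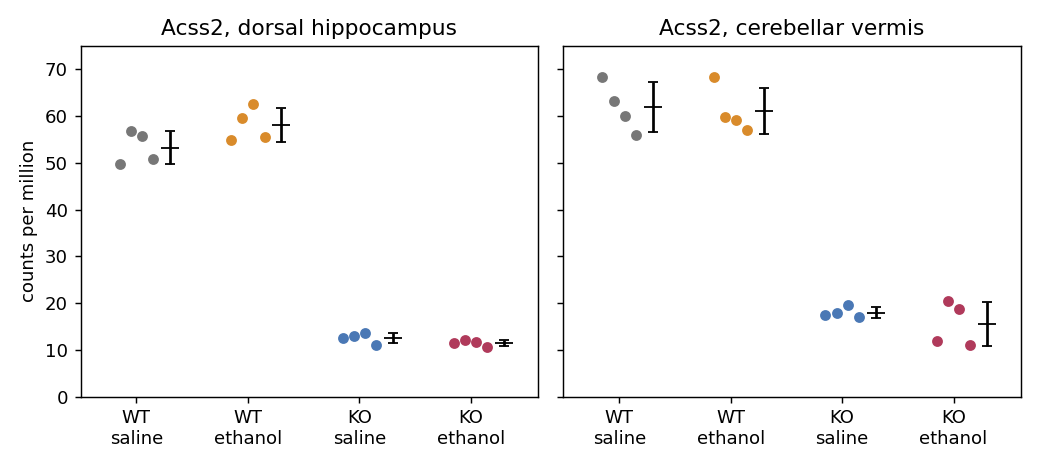
Acss2 in CPM (vertical axis) in each of the 32 libraries, by group (horizontal axis), in dorsal hippocampus and vermis. Points are libraries, and lines give the mean and SD of 4. The highest KO library measured 20.4 CPM and the lowest WT library 49.7 CPM.

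The first comparison asked which hippocampal genes differed after prenatal ethanol in wild-type mice. No gene passed in edgeR, with 0 of 23394 genes at a false discovery rate of 0.05, 2457 at an unadjusted p under 0.05 and 128 called by DESeq2. The 5 genes with the smallest p-values were Lamc1, a laminin chain of basement membranes, Sstr2, a somatostatin receptor, Clic5, Tjap1 and Map3k6, a stress-activated kinase. Their log2 fold changes were 0.40, 0.82, 0.66, 0.39 and 1.29. Sstr2 measured 13.2 ± 2.31 CPM (SD, n = 4) after ethanol and 7.45 ± 0.311 CPM after saline (adjusted p = 0.143). Of 20 glucocorticoid-responsive genes 17 had positive fold changes (median log2 0.22), and 6 were higher when adjusted over the list alone. These included Tsc22d3, an anti-inflammatory target of the glucocorticoid receptor (log2 0.35 ± 0.093 SE) and Hif3a (0.78 ± 0.22). The camera test of the list gave an adjusted p = 9.27e-05, and adjusted p = 0.176 with an estimated correlation. In the circadian clock list 3 of 19 genes were higher when adjusted over the list alone, Per3, Cry1 and Per2, transcriptional repressors of the clock, at log2 0.37, 0.46 and 0.46 (list adjusted p = 0.0126, and adjusted p = 0.473 with an estimated correlation). The clock call was lost without WT ethanol M3 (median 0.035, adjusted p = 0.114) and with an offset for transcript length (0.054). The circadian clock median was 0.044 without saline WT M3 and 0.15 without ethanol WT F3, and that of the glucocorticoid-responsive genes 0.12 without saline WT F1. Of 27 genes of proliferation and new neurons 23 had positive fold changes (median 0.21) and 4 were higher over the list alone, Draxin, Mcm3, Dcx and Sox11 (adjusted p = 0.000104, and adjusted p = 0.176 with an estimated correlation).

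Genes of protein synthesis and respiration had lower values in the same comparison. Of 77 cytosolic ribosomal proteins 71 had negative fold changes (median log2 -0.17) and 22 were lower when adjusted over the list alone, such as Rpl36a (-0.39 ± 0.087 SE). Likewise 68 of 76 genes of nuclear-encoded oxidative phosphorylation were negative (median -0.17) and 19 were lower over the list alone, such as Ndufa5 (-0.53 ± 0.11). Their camera tests gave adjusted p = 1.23e-18 and 4.49e-17, and with an estimated correlation adjusted p = 0.473 for both. All 15 mitochondrially encoded transcripts were negative (median -0.18) and 9 were lower over the list alone (adjusted p = 1.99e-08, and adjusted p = 0.315 with an estimated correlation). The mean of the cytosolic ribosomal proteins was 6.52 and 6.37 log2 CPM in saline WT M3 and F3 against 6.16 and 6.18 in M1 and F1. M3 also stood highest on the third principal component (44.1). Without it the medians of the cytosolic ribosomal proteins and of nuclear-encoded oxidative phosphorylation were -0.11 and -0.10. With an offset for transcript length they were -0.054 and -0.055, and that of the mitochondrially encoded transcripts -0.084. Among 40 activity-regulated genes 4 were lower over the list alone, Npas4 (-0.63 ± 0.13), Gadd45b (-0.42), Fos (-0.80) and Egr2 (-1.09), early transcripts of neuronal firing (adjusted p = 0.00301, and adjusted p = 0.473 with an estimated correlation). That call was lost without WT ethanol F3 (adjusted p = 0.0754). Without saline WT M1 the whole comparison called 21 genes, 2 higher and 19 lower.

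Markers of several cell types also passed with camera after ethanol in WT hippocampus, with no gene passing over all genes. Those of pericytes and vascular smooth muscle were positive in 13 of 13 genes (median log2 0.24), with 0 passing when adjusted over the list alone (adjusted p = 0.000104, and adjusted p = 0.176 with an estimated correlation). Those of the endothelium were positive in 15 of 17 (median 0.12), 2 passing over the list alone (adjusted p = 0.000735, and adjusted p = 0.579 with an estimated correlation). Markers of neocortical neurons outside the hippocampus were positive in 13 of 15 (median 0.31), 2 passing over the list alone (adjusted p = 0.00162, and adjusted p = 0.176 with an estimated correlation). Those of dentate granule neurons were positive in 11 of 13 (median 0.11, 0 passing, adjusted p = 0.0164, and adjusted p = 0.725 with an estimated correlation) and of oligodendrocyte precursors in 10 of 11 (median 0.14, 1 passing, adjusted p = 0.00321, and adjusted p = 0.583 with an estimated correlation). The call of the dentate granule neurons was lost without saline WT F1 (median 0.043), and their median was 0.19 without saline WT F3 or ethanol WT F1. The median of the oligodendrocyte precursors was 0.20 without saline WT M3 and 0.062 without saline WT F3.

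Further marker lists of the same comparison follow, of which no member passed over all genes or, apart from 1 lower microglia marker, over the list alone. Those of blood cells were positive in 5 of 5 genes (median log2 0.81, adjusted p = 0.0158, and adjusted p = 0.6 with an estimated correlation), a call lost without ethanol WT F3 (0.52). Those of oligodendrocytes and myelin were so in 16 of 19 (median 0.24, adjusted p = 0.0193, and adjusted p = 0.87 with an estimated correlation), a call lost without saline WT M1 (0.15) or F3 (0.15) or ethanol WT M1 (0.19) or F3 (0.22). The lists of the choroid plexus (17 of 17 positive, median 0.49) and of ependyma and motile cilia (16 of 16, median 0.48) did not pass (adjusted p = 0.152 and 0.504, and adjusted p = 0.885 and 0.943 with an estimated correlation). Their medians were -0.41 and -0.42 without ethanol WT F3 and 0.053 and 0.27 without saline WT F3. They were 0.85 and 0.81 without ethanol WT M3, where both passed, and 1.16 and 0.85 without saline WT F1, where the first did. Microglia markers were negative in 14 of 20 (median -0.042, adjusted p = 0.0128, and adjusted p = 0.66 with an estimated correlation), a call lost without saline WT M3 (-0.045) or ethanol WT F3 (-0.011). Their median was -0.064 without saline WT M1, -0.081 without ethanol WT M3 and -0.067 without ethanol WT F1.

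In KO hippocampus 12 genes differed after ethanol, 5 higher and 7 lower (chance stays open). Unadjusted p was under 0.05 for 2177, and DESeq2 called 113 (40 higher, 73 lower). Higher were Kcnj2, an inward rectifier potassium channel (11.6 ± 1.93 CPM after saline and 20.9 ± 2.38 after ethanol, SD, n = 4, 1.81-fold, adjusted p = 0.0475), and Pdia6, a disulfide isomerase of the endoplasmic reticulum (1.47-fold). Lower were Nfkbia, the inhibitor of NF-kappaB (21.2 ± 1.01 and 14.3 ± 0.956 CPM, 0.675-fold, adjusted p = 0.00959), Polr3e, an RNA polymerase III subunit (0.699-fold), and Tsc22d3 (0.679-fold). The same held for Dbp, a clock output transcription factor (56.1 ± 6.93 and 36.3 ± 5.21 CPM, 0.646-fold). Of 20 glucocorticoid-responsive genes 16 had negative fold changes (median log2 -0.28), 1 fell over all genes and 8 when adjusted over the list alone, among them Tsc22d3, Ddit4 (-0.50 ± 0.089 SE), Hif3a (-1.26 ± 0.23) and Per1 (-0.59 ± 0.11). That list passed with camera (adjusted p = 1.77e-08) and kept its call with an estimated correlation (adjusted p = 0.0468). In the circadian clock list, 1 of 19 genes fell over all genes and 7 over the list alone, among them Dbp, Nr1d1, Per1 and Ciart (list median -0.12, adjusted p = 5.79e-05, and adjusted p = 0.346 with an estimated correlation). The circadian clock median was -0.27 without saline KO M1, -0.24 without ethanol KO M1, -0.054 without ethanol KO F1 and -0.18 without ethanol KO F3. That of the glucocorticoid-responsive genes was -0.15 without ethanol KO M1.

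Chaperone genes had higher values in the ethanol-exposed KO hippocampus. Of 26 genes of the heat shock and unfolded protein response 24 had positive fold changes (median log2 0.24), 1 rose over all genes and 11 over the list alone, such as Pdia6, Xbp1 (0.42 ± 0.099 SE) and Manf (0.47 ± 0.11) (adjusted p = 4.94e-13, and adjusted p = 0.216 with an estimated correlation). Microglia markers were positive in 19 of 20 genes (median 0.14), with 3 higher over the list alone, P2ry13, Cx3cr1 and P2ry12 (adjusted p = 2.91e-07, and adjusted p = 0.503 with an estimated correlation). Markers of oligodendrocytes and myelin were positive in 19 of 19 genes (median 0.38, adjusted p = 4.68e-06, and adjusted p = 0.637 with an estimated correlation). Those of the choroid plexus were positive in 17 of 17 (median 1.61, adjusted p = 0.00335, and adjusted p = 0.727 with an estimated correlation). No member of either list passed over all genes or over the list alone. The mean of the choroid plexus list ranged from -1.06 to 3.99 log2 CPM over the saline KO libraries and from 0.81 to 5.15 over the ethanol ones. Without ethanol KO F1, which lay farthest from 0 on the first principal component (-59.1), the adjusted p values were 0.0565 for the oligodendrocyte list and 0.372 for the choroid plexus. The choroid plexus list also lost its call without saline KO F3 (0.251) and ethanol KO M3 (0.0964). Without ethanol KO F1 the medians were 0.13 for oligodendrocytes and myelin, 0.82 for the choroid plexus and 0.072 for microglia, and without saline KO F3 that of oligodendrocytes and myelin was 0.21. Markers of blood cells were positive in 5 of 5 genes (median 1.24), those of ependyma and motile cilia in 16 of 16 (1.18) and those of striatal neurons in 14 of 14 (0.84), with none passing over all genes or over the list alone (adjusted p = 0.00354, 0.00241 and 0.00439, and adjusted p = 0.637, 0.693 and 0.693 with an estimated correlation). All 3 calls were lost without ethanol KO F1 (0.46, 0.53 and 0.34). The calls of ependyma and motile cilia and of striatal neurons were also lost without ethanol KO M3 (0.76 and 0.59), the former without saline KO F3 (0.73) and the latter without saline KO F1 (0.73). The median of ependyma and motile cilia was 1.98 without saline KO M1.

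The count of 12 genes in ethanol-exposed KO hippocampus depended on single libraries. It was 0 without saline KO M3 or ethanol KO M1, 2 without saline WT M1 or F3 or ethanol WT M1, M3 or F1, 3 without ethanol KO M3 or F1, and 4 without saline KO M1. It was 5 without saline WT F1 or saline KO F3, 7 without saline KO F1, and 19 without ethanol WT F3 or ethanol KO F3. None was higher without saline WT M1 or F3, ethanol WT M1, M3 or F1, saline KO M1, or ethanol KO M3 or F1. Kcnj2 lost its call in 14 of 26 alternatives, and Pdia6 and Tsc22d3 in 15 each.

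Without ethanol, KO and WT hippocampus differed at Acss2 alone, which stood at 0.236 of the WT level (adjusted p = 7.27e-11). At an unadjusted p under 0.05 there were 2070 genes, and DESeq2 called 195. The next smallest p-values belonged to respiratory chain genes, Cox6c (98.5 ± 13.3 CPM in WT and 65.5 ± 2.29 in KO, SD, n = 4, log2 -0.59, adjusted p = 0.0502), Atp5mg (-0.61), Ndufa4 (-0.58) and Ndufa5 (-0.67). Of 76 genes of nuclear-encoded oxidative phosphorylation 63 had negative fold changes (median log2 -0.26) and 44 were lower when adjusted over the list alone, as were 38 of the 77 cytosolic ribosomal proteins (median -0.21), including Rpl36a (-0.48 ± 0.087 SE). The camera tests gave adjusted p = 1.72e-30 and 2.6e-25, and for both adjusted p = 0.469 with an estimated correlation. The saline WT libraries M3 and F3, with means of 6.52 and 6.37 log2 CPM for the cytosolic ribosomal proteins, are the reference here too. Without M3 the median of the cytosolic ribosomal proteins was -0.12. With an offset for transcript length it was -0.12 as well, and that of nuclear-encoded oxidative phosphorylation -0.16. Markers of pericytes and vascular smooth muscle were positive in 13 of 13 genes (median 0.45), with 5 higher over the list alone (adjusted p = 4.02e-09, and adjusted p = 0.0772 with an estimated correlation). Among them were Kcnj8 (0.79 ± 0.19), a potassium channel of pericytes, and Myh11 (0.74 ± 0.20). In the sterol synthesis list 22 of 24 genes were positive (median 0.12), and none passed over all genes or over the list alone (adjusted p = 0.000633, and adjusted p = 0.76 with an estimated correlation). The list lost its call without saline KO F1 (median 0.057, adjusted p = 0.114). Markers of dentate granule neurons were positive in 12 of 13 genes (median 0.39), while those of the choroid plexus were negative in 16 of 17 (-0.78), of ependyma and motile cilia in 16 of 16 (-0.59) and of striatal neurons in 13 of 14 (-0.69), with none passing over all genes or over the list alone. Camera gave adjusted p = 0.000114, 0.0195, 0.00154 and 0.00576, and with an estimated correlation adjusted p = 0.489, 0.837, 0.837 and 0.837. Without saline WT F1 the medians were 0.20, -0.24 (call lost), -0.34 and -0.30 (call lost). The choroid plexus list also lost its call without saline WT M1 (-0.60), saline KO F1 (-0.38) or saline KO F3 (-0.31), and its median was -1.52 without saline KO M1. The ependyma list lost its call without saline KO F3 (-0.27), and its median was -0.34 without saline KO F1 and -1.32 without saline KO M1. The striatal list lost its call without saline WT M3 (-0.42). Leaving out saline WT M1 gave 92 genes, 4 higher and 88 lower, and leaving out ethanol WT F1, saline KO F1 or ethanol KO F3 gave 2.

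Among ethanol-exposed mice, KO and WT differed at 40 hippocampal genes, 14 higher and 26 lower in KO. At an unadjusted p under 0.05 there were 2320, and DESeq2 called 233 (113 higher and 120 lower). With only the groups compared 8 passed, 0 higher and 8 lower. The lower genes included clock and glucocorticoid-responsive genes. Dbp measured 74.2 ± 5.79 CPM in WT and 36.3 ± 5.21 in KO (SD, n = 4, 0.488-fold, adjusted p = 0.000496), Per1 90.9 ± 8.77 and 55.8 ± 9.10 CPM (0.613-fold, adjusted p = 0.0173) and Hif3a 7.88 ± 2.16 and 2.13 ± 0.350 CPM (0.271-fold, adjusted p = 0.00352). Also lower were Ciart (0.455-fold), Per3 (0.713-fold) and Nr1d1 (0.67-fold), repressors within the clock. Tsc22d3 (0.654-fold), Klf15, a glucocorticoid-induced transcription factor (0.687-fold), Nfkbia (0.719-fold), Polr3e (0.719-fold) and Acss2 itself (0.197-fold) were lower too. Higher were Calr, a calcium-binding chaperone (253 ± 8.40 and 360.0 ± 44.1 CPM, 1.42-fold, adjusted p = 0.0122), Pdia6 (1.5-fold), Cldn5, the tight junction protein of endothelium (1.92-fold), and Cx3cr1, the microglial fractalkine receptor (1.24-fold). So were Sox2, a stem cell transcription factor (1.37-fold), Gsta4 (1.32-fold) and Myo5b (1.51-fold). Sox2 and Cx3cr1 each lost their calls in 18 of 26 alternatives, Myo5b in 12 and Cldn5 in 11. All 4 were lost with no sex term and with the replicate label as a block, and Sox2 with an offset for transcript length.

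By list, 4 of 20 glucocorticoid-responsive genes fell over all genes in that comparison, while 12 were lower and 1 higher when adjusted over the list alone, including Sgk1, a glucocorticoid-induced kinase (log2 -0.83 ± 0.14 SE, list median -0.26). The list passed with camera (adjusted p = 2.94e-09) and with an estimated correlation (adjusted p = 0.0337). Of 19 circadian clock genes 5 fell over all genes, and 8 were lower and 2 higher over the list alone (median -0.13, adjusted p = 4.94e-08, and adjusted p = 0.12 with an estimated correlation). Per1 belongs to both lists. The heat shock and unfolded protein response was positive in 24 of 26 genes (median 0.24), with 1 higher over all genes and 13 over the list alone, such as the chaperones Hspa8 (0.35 ± 0.075) and Hspa5 (0.62 ± 0.14) (adjusted p = 8.28e-13, and adjusted p = 0.151 with an estimated correlation). Microglia markers were positive in 18 of 20 genes (median 0.19), with 1 higher over all genes and 6 over the list alone, including P2ry13 (0.40) and P2ry12 (0.30) (adjusted p = 1.49e-08, and adjusted p = 0.316 with an estimated correlation). The circadian clock median was -0.24 without ethanol WT F3 and -0.23 without ethanol KO M1. That of the heat shock and unfolded protein response was 0.15 without ethanol KO M3, and that of microglia 0.11 without ethanol KO F1. The count of 40 genes was 6 without ethanol WT M3 (0 higher), 7 without ethanol WT M1 (0 higher) or F1 (1 higher), 18 without ethanol KO F3, 20 without ethanol KO F1 and 23 without ethanol KO M3.

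The exposure effect differed between genotypes at 41 hippocampal genes in the test of the interaction, KO ethanol against saline minus WT ethanol against saline. Of these 9 had positive and 32 negative terms, with 2326 genes at an unadjusted p under 0.05 and 272 by DESeq2 (71 positive and 201 negative). Tsc22d3 went from 49.8 ± 3.03 CPM after saline to 63.3 ± 3.62 after ethanol in WT (SD, n = 4) and from 61.1 ± 11.9 to 41.5 ± 2.82 in KO (interaction log2 -0.91 ± 0.13 SE, adjusted p = 0.0223). Negative terms were also found for Polr3e (-0.74 ± 0.096, adjusted p = 0.0157), Hif3a (-2.04), Sgk1 (-1.19), Per1 (-0.84), Per3 (-0.63), and Nfkbia (-0.66). Others were Tet3, which oxidises methylated cytosine (-0.66), and Slc7a5, an amino acid transporter (-0.68). Positive terms included Npas4, an activity-dependent transcription factor (10.6 ± 2.05 to 6.86 ± 0.560 CPM in WT and 7.95 ± 1.05 to 10.6 ± 0.998 in KO, log2 1.05, adjusted p = 0.0493). Sox2 was at 0.67 and Fgf10 at 1.17. Of the 20 glucocorticoid-responsive genes 5 had negative terms over all genes and 12 over the list alone (median -0.48). The list held with camera (adjusted p = 4.2e-11) and an estimated correlation (adjusted p = 0.0185). Of 19 circadian clock genes 2 had negative terms over all genes and 7 over the list alone (median -0.25, adjusted p = 1.75e-06, and adjusted p = 0.166 with an estimated correlation), Dbp among the latter (-0.74 ± 0.15). All 15 mitochondrially encoded transcripts had positive terms (median 0.36), 13 of them passing over the list alone (adjusted p = 8.16e-13, and adjusted p = 0.209 with an estimated correlation). Microglia markers were positive in 19 of 20, with P2ry12, P2ry13 and Cx3cr1 passing over the list alone (3 of 20, median 0.20, adjusted p = 5.7e-08, and adjusted p = 0.323 with an estimated correlation). Sgk1, Per1, Npas4, Sox2 and Fgf10 each lost their calls in 16 to 18 of 26 alternatives, 1 of them for Sgk1 the offset for transcript length. The microglia median was 0.10 when saline WT M3 and ethanol KO F1 were both left out. The count of 41 was smaller in each of the 16 fits that left out 1 library. It was 0 without ethanol WT F1 or saline KO M3, 1 without ethanol WT M3, 2 without ethanol WT M1 or saline KO F3, 6 without saline WT F3 or saline KO M1, and 7 without saline WT M3 or ethanol KO M1. It was 9 without ethanol KO M3, 12 without ethanol KO F1 or F3, 14 without saline KO F1, 15 without saline WT F1, 21 without ethanol WT F3 and 24 without saline WT M1. No positive term passed without saline WT M3 or F3, ethanol WT M1 or M3, saline KO M1 or F3, or any 1 of the ethanol KO libraries.

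**Figure D2:**
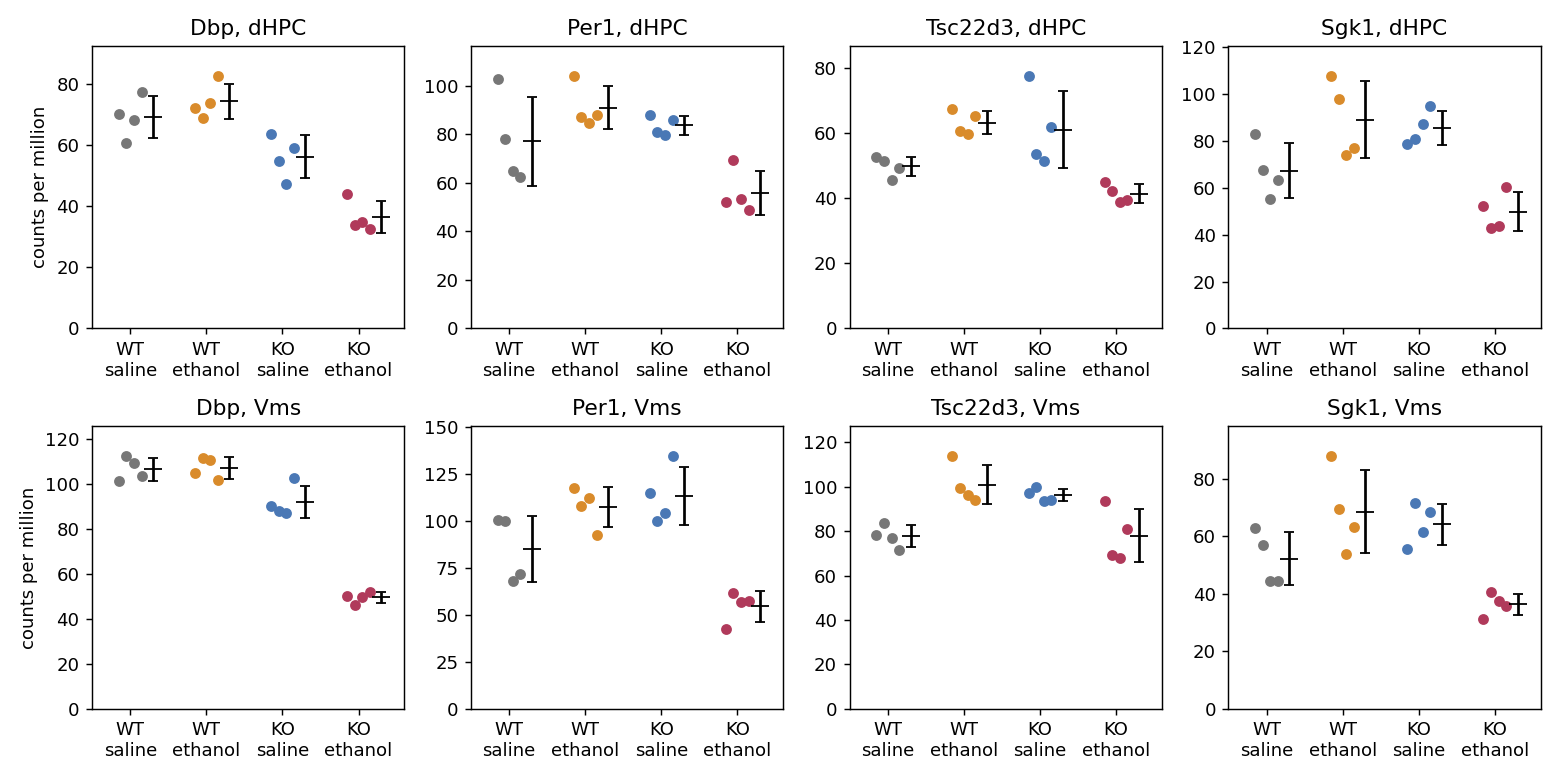
CPM (vertical axis) of Dbp, Per1, Tsc22d3 and Sgk1 in each library, by genotype and exposure (horizontal axis), in hippocampus and vermis. Points are libraries, and lines give the mean and SD of 4. In the vermis the ethanol-exposed KO libraries averaged 49.5 CPM for Dbp and 36.2 CPM for Sgk1, against 107 and 68.6 CPM in ethanol-exposed WT.

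In wild-type vermis 1 gene of 22441 differed after prenatal ethanol, with 1194 at an unadjusted p under 0.05 and 17 by DESeq2. This was Mt2, a metal-binding metallothionein, which rose from 77.8 ± 6.91 to 123.5 ± 12.2 CPM (SD, n = 4, 1.59-fold, adjusted p = 0.0312). Next by p-value were Frmd6, a regulator of Hippo signalling (log2 0.60), Dusp6, a phosphatase of ERK kinases (0.59), Mt1 (0.39) and Tet2 (-0.38), each at adjusted p = 0.399. The list of 20 glucocorticoid-responsive genes, which holds Mt1 and Mt2, had 17 positive fold changes (median log2 0.39), with 1 gene higher over all genes and 9 over the list alone, including Tsc22d3 (0.38 ± 0.081 SE) and Cdkn1a (0.61 ± 0.14). It passed with camera (adjusted p = 9.69e-13) and with an estimated correlation (adjusted p = 0.0174). The circadian clock list was positive in 16 of 19 genes (median 0.11), none passing over all genes or over the list alone (adjusted p = 0.000814, and adjusted p = 0.684 with an estimated correlation). In the saline group, F1 carried 5.99% ribosomal RNA (95% Wilson interval 5.98% to 5.99%) against 0.591% to 0.630% in the other libraries. The call of Mt2 was absent (0 genes) without saline WT M3, F1 or F3, ethanol WT M1, M3 or F1, or saline KO F3. Without ethanol KO F1 2 genes passed.

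In KO vermis 20 genes differed after ethanol, 5 higher and 15 lower (chance stays open). Unadjusted p was under 0.05 for 2993, and DESeq2 called 213 (90 higher, 123 lower). Dbp fell from 91.9 ± 7.32 to 49.5 ± 2.50 CPM (SD, n = 4, 0.539-fold, adjusted p = 8.72e-06), Per1 from 113 ± 15.4 to 54.4 ± 8.32 CPM (0.48-fold, adjusted p = 0.0237) and Sgk1 from 64.2 ± 7.19 to 36.2 ± 3.78 CPM (0.564-fold, adjusted p = 0.0338). Ciart (0.607-fold), Nr1d1 (0.621-fold), Mt2 (0.685-fold), Frmd6 (0.588-fold), Map3k6 (0.402-fold), Klf2, a vascular transcription factor (0.571-fold), Nfkbia (0.715-fold), and Slc7a5 (0.744-fold) also fell. Kank1, a regulator of the cytoskeleton, rose from 24.3 ± 1.23 to 33.2 ± 0.780 CPM (1.37-fold, adjusted p = 0.00318), as did Cldn5 (1.59-fold), Zfp36l2, an RNA decay factor (1.66-fold), and Mmp14, a membrane-bound protease (1.44-fold). Of 19 circadian clock genes 5 fell over all genes and 10 over the list alone (median log2 -0.23). Of 20 glucocorticoid-responsive genes 4 fell over all genes and 10 over the list alone, with Ddit4 at -0.45 ± 0.075 SE (median -0.21). Their camera tests gave adjusted p = 7.33e-10 and 4.47e-08, and both had adjusted p = 0.0515 with an estimated correlation. The median of the glucocorticoid-responsive genes was -0.34 without ethanol KO M3. Zfp36l2, Mmp14, Slc7a5 and Ddit4 each lost their calls in 14 to 18 of 26 alternatives, and with only the groups compared 0 genes were higher and 1 lower.

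In KO vermis after ethanol, markers of Purkinje neurons were negative in 23 of 24 genes (median log2 -0.35). Those of cerebellar granule neurons were negative in 19 of 20 (median -0.32). Markers of oligodendrocytes and myelin were positive in 19 of 19 genes (median 0.57). Microglia markers were positive in 20 of 20 (median 0.45), with Siglech (0.68 ± 0.17 SE) higher over the list alone, and those of the brainstem and deep nuclei in 20 of 21 (median 3.74). Apart from Siglech, no gene of these lists passed over all genes or over the list alone. The camera tests gave adjusted p = 7.13e-07, 5.47e-05, 3.17e-07, 1.17e-06 and 0.000355 in that order, and adjusted p = 0.599 for each with an estimated correlation. In F1 the Purkinje neurons list averaged 6.82 log2 CPM, against 7.64 to 8.12 in the other ethanol-exposed KO libraries. F1 lay farthest out on the first principal component (102.7). Without F1 the list medians were -0.11 for Purkinje neurons, -0.06 for granule neurons (adjusted p = 0.0964), 0.15 for oligodendrocytes, 0.17 for microglia and 1.54 for brainstem and deep nuclei (adjusted p = 0.0704). Without F3 the medians were -0.63 for Purkinje neurons and -0.60 for cerebellar granule neurons. The count of 20 genes was 2 without saline KO M3 or ethanol KO M3, 5 without saline KO F3, and 8 without ethanol KO M1. It was 9 without saline KO M1, 10 without saline KO F1, 13 without ethanol WT M3 and 616 without ethanol KO F3, the shallowest library.

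In saline vermis KO differed from WT at 1102 genes, 1038 higher and 64 lower. Unadjusted p was under 0.05 for 3152, and DESeq2 called 1505 (1317 higher, 188 lower). Of the 1102, 774 were protein-coding and 282 pseudogenes, whose reads are shared with their parent genes. Rpl35a measured 30.8 ± 2.73 CPM in WT and 66.3 ± 2.32 in KO (SD, n = 4, 2.15-fold, adjusted p = 7.93e-07), Rps14 56.8 ± 6.72 and 140.0 ± 17.8 CPM (2.47-fold, adjusted p = 9.44e-07) and Atp5f1e, a subunit of ATP synthase, 28.9 ± 2.56 and 62.4 ± 4.41 CPM (2.16-fold, adjusted p = 7.93e-07). Rpl26 (1.97-fold), Rps25 (1.85-fold) and Uqcc2, an assembly factor of complex III (1.87-fold), rose too. So did Cox7a2 and Pfdn5 (both 1.91-fold). Lower were Acss2 (0.291-fold, adjusted p = 6.91e-06), Bach2, a transcriptional repressor (22.0 ± 2.36 and 10.9 ± 1.81 CPM, 0.493-fold, adjusted p = 8.95e-05), and Slc2a13, the proton myo-inositol cotransporter (0.504-fold).

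Of the 77 cytosolic ribosomal proteins 74 rose over all genes in saline-exposed KO vermis and 76 when adjusted over the list alone (median log2 0.72). Of 76 genes of nuclear-encoded oxidative phosphorylation 68 and 71 rose (median 0.50), such as Atp5mg (0.93 ± 0.067 SE). Both lists passed with camera (adjusted p = 1.57e-113 and 3.16e-87) and with an estimated correlation (adjusted p = 0.0344 and 0.026). Short transcripts were higher in general, with a median log2 fold change of 0.30 over 486 genes of 500 to 1000 nucleotides and -0.037 over the 4093 genes of the class of long transcripts next to the longest. With an offset for transcript length the list medians were 0.48 and 0.32, and 642 genes passed, 529 higher and 113 lower. Markers of meninges and fibroblasts were positive in 19 of 19 genes (median 0.57), with Col3a1, a fibrillar collagen (0.81 ± 0.18), higher over all genes and over the list alone (adjusted p = 4.5e-06, and adjusted p = 0.966 with an estimated correlation). Of 20 glucocorticoid-responsive genes 4 rose over all genes and 6 over the list alone (median 0.16), including Mt2 (0.63 ± 0.086), Mt1 (0.43 ± 0.075), Cdkn1a (0.68 ± 0.14) and Tsc22d3 (0.31 ± 0.081) (adjusted p = 0.00061, and adjusted p = 0.334 with an estimated correlation). With the length offset Mt2 (0.26), Mt1 (0.24) and Tsc22d3 (0.30) lost their calls, and Cdkn1a (0.67) kept its.

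**Figure D3:**
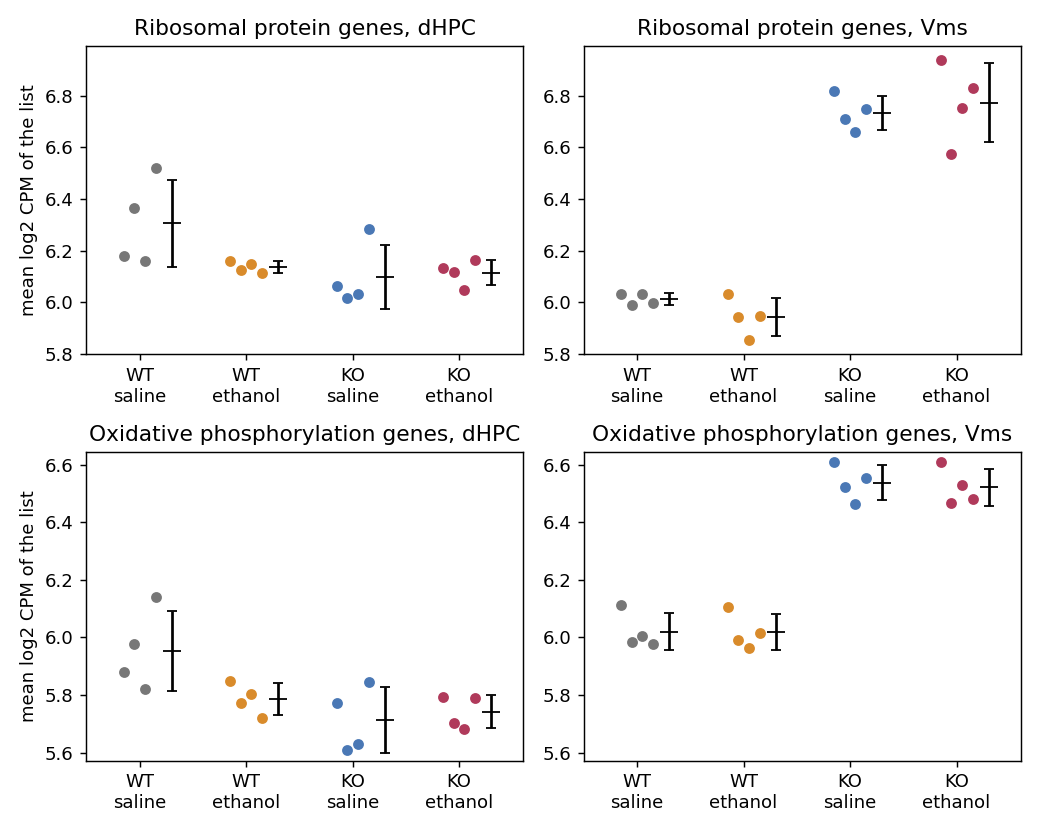
Mean log2 CPM (vertical axis) over the cytosolic ribosomal proteins and over nuclear-encoded oxidative phosphorylation genes in each library, by genotype and exposure (horizontal axis), in hippocampus and vermis. Points are libraries, and lines give the mean and SD of 4. In the vermis the ribosomal mean was 6.57 to 6.94 in the 8 KO libraries and 5.85 to 6.03 in the 8 WT libraries.

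In ethanol vermis KO differed from WT at 1690 genes, 1287 higher and 403 lower. Unadjusted p was under 0.05 for 5732, and DESeq2 called 3013 (1758 higher, 1255 lower). Of the 1690, 1324 were protein-coding and 265 pseudogenes. Rpl35a (2.54-fold, adjusted p = 1.15e-07), Rps14 (2.82-fold), Rpl39 (2.81-fold), Rps3 (2.29-fold), Uqcc2 (2.18-fold), Pfdn5 (2.13-fold), and Atp5f1e (2.06-fold) rose. Rps3 measured 80.2 ± 3.81 CPM in WT and 183.5 ± 14.9 in KO (SD, n = 4). Dbp fell from 107 ± 4.67 to 49.5 ± 2.50 CPM (0.462-fold, adjusted p = 1.37e-07), and Ciart from 16.2 ± 0.833 to 7.77 ± 1.25 CPM (0.479-fold, adjusted p = 3.94e-06). Mertk, a receptor for the clearance of dying cells, fell from 28.4 ± 4.36 to 15.1 ± 0.655 CPM (0.536-fold, adjusted p = 3.48e-05). Lower, too, were Acss2 (0.252-fold), Nr1d1 (0.599-fold), Nr1d2 (0.707-fold), Per3 (0.631-fold), Tef, a clock output factor related to Dbp (0.7-fold), Klf15 (0.655-fold) and Map3k6 (0.363-fold).

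The cytosolic ribosomal proteins rose in 76 of 77 genes over all genes in that comparison and in 76 over the list alone (median log2 0.82), and nuclear-encoded oxidative phosphorylation in 62 and 69 of 76 genes (median 0.50), such as Ndufa12 (0.84 ± 0.057 SE). With the length offset the medians of these lists were 0.56 and 0.33, and Atp5f1e was at 0.67 in place of 1.04. The 486 genes of 500 to 1000 nucleotides had a median of 0.32, and ribosomal matches by most counts per base 0.031. Of 19 circadian clock genes 11 fell over all genes and 11 over the list alone (median -0.35). Of 20 glucocorticoid-responsive genes 6 fell over all genes, while 11 were lower and 1 higher over the list alone (median -0.30), Sgk1 at -0.91 ± 0.13 and Hif3a at -2.27 ± 0.35 among them. Camera gave adjusted p = 7.1e-87, 5.49e-55, 1.32e-09 and 3.82e-07 for these lists, and each of them passed with an estimated correlation (adjusted p = 0.0444). Microglia markers were positive in 20 of 20 genes (median 0.58), with 4 higher over all genes and 11 over the list alone, including Tyrobp (1.46 ± 0.24) and Aif1 (1.22 ± 0.29) (adjusted p = 1.11e-05, and adjusted p = 0.623 with an estimated correlation). The microglia median was 0.30 without ethanol KO F1, and Aif1 lost its call with an offset for transcript length (0.95). Markers of meninges and fibroblasts were positive in 18 of 19 (median 0.66), with 5 higher over all genes and 8 over the list alone, including Col1a1 (0.94 ± 0.22) (adjusted p = 1.7e-05, and adjusted p = 0.623 with an estimated correlation). Markers of Purkinje neurons were negative in 22 of 24 (median -0.35), those of cerebellar granule neurons in 19 of 20 (-0.48), with none passing over all genes or over the list alone. Those of oligodendrocytes and myelin were positive in 19 of 19 (0.47), 1 passing over all genes and 0 over the list alone, those of the choroid plexus in 15 of 17 (1.31), 3 passing over all genes and over the list alone, and those of ependyma and motile cilia in 13 of 14 (1.55), with none passing. Camera gave adjusted p = 0.000333, 3.27e-05, 0.0045, 0.00702 and 0.0186 for these 5 lists, and with an estimated correlation adjusted p = 0.712, 0.623, 0.712, 0.506 and 0.712. Without ethanol KO F1 the medians were -0.10 (call lost), -0.26, 0.056 (call lost) and 0.86 for the lists from Purkinje neurons to choroid plexus. Without ethanol KO F3 they were -0.59 and -0.77 for Purkinje neurons and cerebellar granule neurons, and without ethanol KO M1 the ependyma list lost its call (1.17). The count of 1690 genes was 973 without ethanol WT M1, 1045 without ethanol WT F3, 1042 without ethanol KO M3 and 5092, of which 2679 were higher, without ethanol KO F3.

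In the vermis the exposure effect differed between genotypes at 24 genes, 3 with positive and 21 with negative terms, with 2524 at an unadjusted p under 0.05 and 241 by DESeq2 (89 positive and 152 negative). Mt2 went from 77.8 ± 6.91 CPM after saline to 123.5 ± 12.2 after ethanol in WT (SD, n = 4) and from 120.6 ± 15.6 to 82.5 ± 7.92 in KO (interaction log2 -1.22 ± 0.12 SE, adjusted p = 0.000681). Dbp stayed near its level in WT (106.5 ± 5.13 and 107 ± 4.67 CPM) and was 91.9 ± 7.32 and 49.5 ± 2.50 CPM in KO (interaction -0.90 ± 0.086, adjusted p = 0.000681). Negative terms were also found for Frmd6 (-1.37), Per1 (-1.40), Sgk1 (-1.22), Nfkbia (-0.70), Klf2 (-1.18), Bdnf, a neurotrophin (-0.87), Spred2 (-1.18), Map3k6 and Dusp6. Positive terms were found for Kank1 (0.55), Mmp14 (0.81) and Adamts1, a secreted protease (1.01). Of 20 glucocorticoid-responsive genes 5 had negative terms over all genes, and 12 negative and 1 positive over the list alone (median -0.64), Tsc22d3 among them (-0.68 ± 0.12). Of 19 circadian clock genes 3 had negative terms over all genes and 12 over the list alone (median -0.37), with Ciart at -0.83 ± 0.14. Both lists passed with camera (adjusted p = 1.56e-14 and 7.1e-12) and with an estimated correlation (adjusted p = 0.0103 and 0.0212). Markers of Purkinje neurons were negative in 22 of 24 genes (median -0.41). Those of cerebellar granule neurons were negative in 18 of 20 (median -0.50). No gene of either list passed over all genes or over the list alone (both adjusted p = 3.55e-05, and adjusted p = 0.772 with an estimated correlation). Without ethanol KO F1 the medians of Purkinje neurons and cerebellar granule neurons were -0.20 and -0.28, and without ethanol KO F3 -0.69 and -0.79. Positive terms were found in 20 of 20 markers of microglia (median 0.47, 1 passing over the list alone), 19 of 19 of oligodendrocytes and myelin (0.55, none passing) and 13 of 14 of ependyma and motile cilia (2.47, none passing), with 0 passing over all genes (adjusted p = 7.38e-05, 0.000151 and 0.00688, and adjusted p = 0.772 for each with an estimated correlation). The medians of microglia and of oligodendrocytes and myelin were 0.19 and 0.11 without ethanol KO F1, and the ependyma list lost its call without saline WT F3 (0.63). The count of 24 genes was 3 without saline WT M1, 4 without saline WT M3, 5 without saline KO M3, 6 without ethanol WT F1 and 7 without saline KO F3. It was 8 without saline WT F1, 9 without ethanol WT M1, 10 without saline WT F3, 14 without ethanol WT F3, 15 without ethanol KO M1 and 168 without ethanol KO F3. No positive term passed without saline WT M1 or ethanol WT F1. Adamts1 lost its call in 14 of 26 alternatives and Spred2 in 15.

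**Figure D4:**
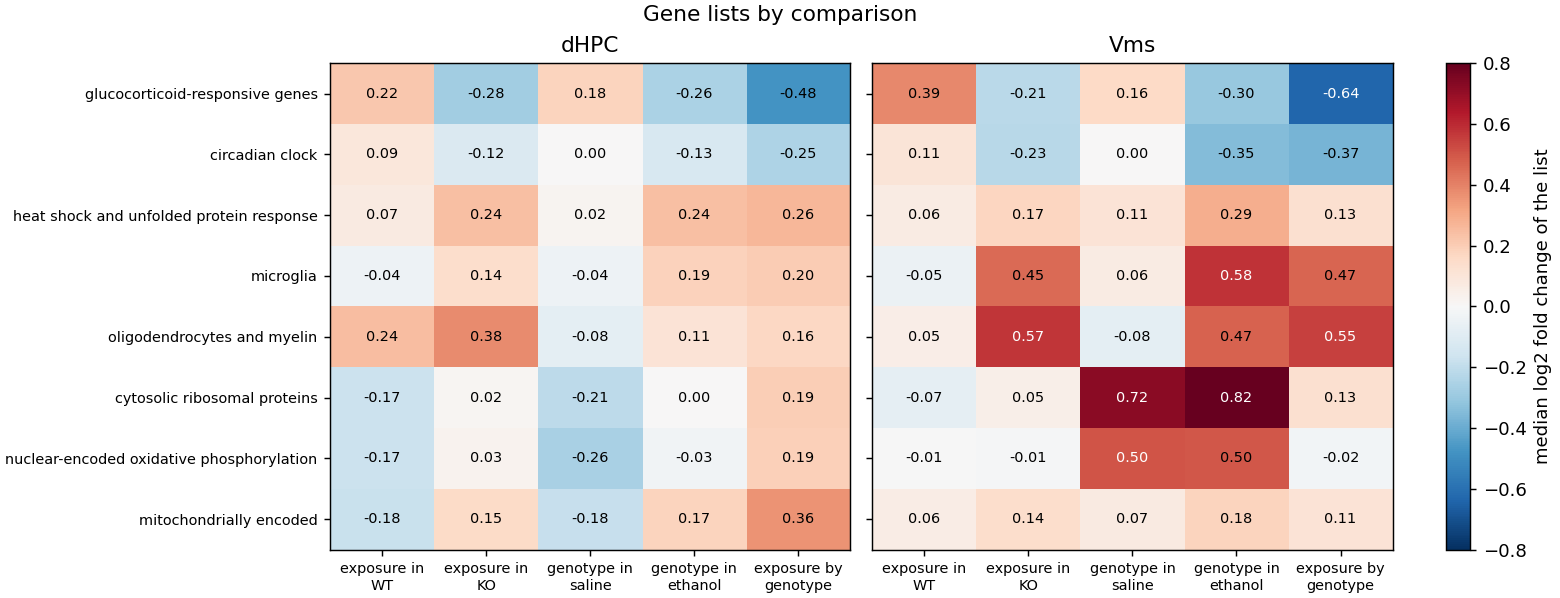
Median log2 fold change (colour) of 8 gene lists (vertical axis) in the 5 comparisons (horizontal axis) of hippocampus and vermis. The cytosolic ribosomal proteins had medians of -0.21 in hippocampus and 0.72 in vermis for genotype in saline, and the glucocorticoid-responsive genes -0.48 and -0.64 for exposure by genotype.

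The comparisons across tissues used the same 16 mice, so shared genes are not from separate animals. For genotype among ethanol-exposed mice, 16 genes were lower in both tissues out of 26 in hippocampus and 399 in vermis, against 0.479 by chance over 21645 genes tested in both. These were Acss2, and the clock genes Ciart, Dbp, Nr1d1, Per1 and Per3. The others were Hif3a, Klf15, Map3k6, Nfkbia, Sgk1, Tsc22d3, Fam83d, Prr5, Slc7a5 and Zfp276. On the higher side 7 of 14 and 1271 were shared, against 0.822 by chance, Calr, Ccdc190, Cldn5, Cysltr2, Gsta4, Pdia6 and Sox2. For exposure by genotype 6 negative genes were shared out of 32 and 21, against 0.031 by chance, Map3k6, Nfkbia, Per1, Sgk1, Slc7a5 and Tsc22d3. For exposure in KO, Dbp and Nfkbia were shared among 7 and 15 lower genes, against 0.00485 by chance. The test of the tissue difference, with mouse as a block, found that the exposure effect in KO differed between tissues at 1 gene of 24458, Slc2a13 (ENSMUSG00000036298, log2 1.05 ± 0.13 SE, adjusted p = 0.0108). It measured 133.8 ± 12.8 and 120.0 ± 17.1 CPM after saline and ethanol in hippocampus and 56.4 ± 6.21 and 104.6 ± 6.29 CPM in vermis (SD, n = 4). At an unadjusted p under 0.05 there were 1474 genes, and DESeq2 called 18. In WT edgeR called 0 genes, with 1217 at an unadjusted p under 0.05 and 1 by DESeq2, and Mt2 had a term of 0.59 ± 0.13 (adjusted p = 0.94). Slc2a13 lost its call without saline KO F1 or F3 or ethanol KO M1 or M3 (0 genes each), and 2 genes passed without ethanol KO F3.

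Whether the exposure effect differed between the sexes was tested in each genotype and tissue. In edgeR 0 genes passed in any of the 4 tests, with 702 and 974 genes at an unadjusted p under 0.05 in WT and KO hippocampus and 397 and 463 in vermis. DESeq2 called 0 in each. The smallest p-values belonged to Gpr89, Zfp36l2, Zfp267 and Hspb1, a small heat shock protein (log2 1.36 ± 0.27 SE in KO vermis), each at adjusted p = 1. Without ethanol WT F1 the hippocampal WT test called 4 genes, and without saline WT F3 the vermis WT test called 21.

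Across genes, the exposure effects of WT and KO had a Pearson r of 0.168 and a Spearman rho of 0.087 over 23394 hippocampal genes, of which 50.5% had the same direction. Over 22441 vermis genes the values were -0.092, -0.146 and 44.4%. Genes are not independent replicates, and no p-value was attached to them. Over genes of at least 10 CPM r was -0.012 in hippocampus and -0.344 in vermis, and the vermis r was 0.085 without saline WT F3 and 0.030 without ethanol WT M1.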

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

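The tests of transcript length, of an effect common to both tissues, of the time of day and of a single library were chosen after the results were seen, while those of meninges, neighbouring tissue and other splits were chosen before. Single libraries stood far from the other 3 of their group in 7 of 88 groups of values, where chance gives about 1 in 20, or 4.4. Saline WT vermis F1 carried 5.99% ribosomal RNA (95% Wilson interval 5.98% to 5.99%) against 0.591% to 0.630% in the others. The mean of the circadian clock list was 5.99 log2 CPM in saline KO vermis M3 against 5.83 to 5.85. The choroid plexus list stood at -0.16 in saline WT hippocampus F3 against 3.37 to 3.94, and at 0.83 in saline KO vermis F3 against -0.77 to -0.56. The Purkinje neurons list stood at 4.21 in saline KO hippocampus M1 against 4.62 to 4.67. Markers of oligodendrocytes and myelin stood at 6.74 in ethanol WT vermis F1 against 6.21 to 6.28, and at 6.19 in saline KO vermis F3 against 6.35 to 6.37. The exposure effect differed between genotypes at 41 genes in hippocampus and 24 in vermis, and between tissues in KO at 1 gene, Slc2a13.

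Cytosolic ribosomal proteins and oxidative phosphorylation genes were higher in KO vermis. Transcript length as the whole cause is argued against, since genes matched in length to each member shifted by 31.7% to 50.8% as much. With the length offset the lists kept at least 63.5% of their medians. All matched genes pooled shifted by 18.2% to 26.7%, or -1.58% to 3.72% with the length of the transcript with most counts per base. How far length may account for a part depends on its definition. Meninges in the dissection are argued against, since the ribosomal median in saline kept 89.4% with the meninges level as a covariate, and an effect of the knockout common to both tissues by the ribosomal median of -0.21 in saline hippocampus. A batch of library preparation that follows genotype in the vermis stays open, since the labels give none, as does an effect of the knockout in the vermis alone, which was not tested apart from it.

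Clock and glucocorticoid-responsive genes had lower values in ethanol-exposed KO in both tissues, but with an estimated correlation the clock list lost its calls in hippocampus (adjusted p = 0.346 for exposure in KO, 0.12 for genotype in ethanol and 0.166 for the interaction) and both lists lost theirs in exposure in KO vermis (adjusted p = 0.0515). Tissue carried over in the dissection is argued against, since the glucocorticoid median of the interaction kept 97.0% in hippocampus and 102% in vermis with the marker level as a covariate. A different time of day at death cannot be told apart from the groups: the 5 clock genes of opposite phase had interaction medians of 0.094 in hippocampus and -0.082 in vermis, while the 10 in-phase genes had -0.52 and -0.72, and the labels give no time. Handling before death, litter and cage, and an effect of ethanol that depends on Acss2 also stay open and were not tested.

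Markers of Purkinje and granule neurons had lower values in ethanol-exposed KO vermis, though no member of either list passed and both list calls were lost with an estimated correlation (adjusted p = 0.599). Without ethanol KO F1 the Purkinje median kept 31.7%, and the granule median went from -0.32 to -0.060. F1 was lowest in Purkinje markers, so this cannot tell whether it alone held other tissue. Without F3 both falls grew. With the brainstem and deep nuclei level as a covariate the Purkinje median kept 56.4%, so a change in the other libraries stays open.

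Whether chance can be excluded was tested on the 35 splits of the 8 libraries of each comparison within a tissue. In hippocampus chance could not be excluded for the count of exposure in WT (real 0, highest other 2, with 35 of 35 splits giving as many), exposure in KO (12 against 28, with 2 splits) or genotype in saline (1 against 7, with 3 splits). It was excluded for genotype in ethanol (40 against 1, with 1 split, the real one). In vermis it was excluded for genotype in saline (1102 against 0). For exposure in WT it was excluded by the share of splits alone (1 against 0), which rests on the single call of Mt2. That call was absent in the fits listed with it above, without a sex term and with the replicate label as a block (0 genes each). The bound was not met for exposure in KO (20 against 2589, 3 splits) or genotype in ethanol (1690 against 4885, 2 splits). The splits with 2589 and 4885 genes each divided the libraries by the sign of the first principal component, whose cause was not tested.

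The medians of the glucocorticoid, clock, ribosomal and oxidative phosphorylation lists were compared with the other splits wherever camera called the list. Except where the report gives them as passing with an estimated correlation, these lists lost their calls with it. This included exposure in WT hippocampus (glucocorticoid list, adjusted p = 0.176) and calls not described in the report: the glucocorticoid list of genotype in saline hippocampus (adjusted p = 0.000633 with camera and 0.422 with an estimated correlation), the ribosomal list of exposure in vermis in WT (2.32e-05 and 0.961) and KO (0.0401 and 0.85) and of the interactions (2.24e-12 and 0.651 in hippocampus, 5.57e-05 and 0.823 in vermis), and the oxidative phosphorylation list of the hippocampal interaction (5.73e-13 and 0.58). For the glucocorticoid-responsive genes the bound was met in hippocampus for exposure in WT (0.22, highest other 0.17), exposure in KO (-0.28 against 0.26), genotype in saline (0.18 against 0.13) and genotype in ethanol (-0.26 against 0.25). In vermis it was met for exposure in WT (0.39 against 0.28) and, by a narrow margin, genotype in ethanol (-0.30 against 0.30). It was not met there for exposure in KO (-0.21 against 0.27, 3 splits) or genotype in saline (0.16 against 0.22, 5 splits). For the circadian clock the bound was not met in any comparison of 35 splits. In hippocampus the medians were 0.091 against 0.17 for exposure in WT (7 splits), -0.12 against 0.24 for exposure in KO (7 splits) and -0.13 against 0.31 for genotype in ethanol (8 splits). In vermis they were 0.11 against 0.12 for exposure in WT (3 splits), -0.23 against 0.28 for exposure in KO (2 splits) and -0.35 against 0.36 for genotype in ethanol (3 splits).

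For the cytosolic ribosomal proteins the bound was met in vermis for genotype in saline (0.72 against 0.46) and ethanol (0.82 against 0.63), and likewise for nuclear-encoded oxidative phosphorylation (0.50 against 0.32, and 0.50 against 0.36). It was not met for ribosomal medians of exposure in vermis, in WT (-0.073 against 0.093, 5 splits) or KO (0.046 against 0.17, 20 splits). In hippocampus it was not met for exposure in WT (ribosomal -0.17 against 0.22, 5 splits, and oxidative phosphorylation -0.17 against 0.24, 4 splits). Nor was it for genotype in saline (-0.21 against 0.29, 5 splits, and -0.26 against 0.27, 3 splits).

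For the interactions 75 splits were drawn. The bound was met for the count in hippocampus (41, highest other 19, 1 split) and, with 2 splits, in vermis (24 against 98). The 98 was not traced. The bound was also met for the glucocorticoid medians (-0.48 against 0.42 in hippocampus, and -0.64 against 0.66 in vermis) and the clock median in vermis (-0.37 against 0.37). An earlier and larger draw also met it for these results, but held splits with medians farther from 0 than the real one for the glucocorticoid list in hippocampus and the clock list in vermis. The bound was not met in hippocampus for the clock (-0.25 against 0.28, 5 splits) or ribosomal medians (0.19 against 0.31, 14 splits). Nor was it for oxidative phosphorylation there (0.19 against 0.32, 13 splits) or the ribosomal list in vermis (0.13 against 0.26, 15 splits). It was not met for the correlations of exposure effects (0.168 against 0.413, 25 splits, and -0.092 against 0.456, 55 splits). For the tissue tests the 10 splits drawn are too few for a share under 0.05, with 1 gene in KO against a highest other of 0 and 0 genes in WT against 0, as many as in all 10. In the earlier and larger draw the real split alone gave a gene in KO, a share under 0.05, and another split gave 1 gene in WT.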

How the results depend on the processing

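The length offset, the restriction to protein-coding genes, the marker covariates and the fits that left out a pair of libraries were chosen after seeing the data, and the other alternatives were planned. The cause was not tested for results that changed, except that fewer libraries were fitted where libraries or groups were left out.

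With no low-count filter, hippocampal counts were 608 (exposure in WT), 928 (exposure in KO), 633 (genotype in saline), 430 (genotype in ethanol), 688 (interaction), 243 and 424 (exposure by sex in WT and KO). Vermis counts were 4 (exposure in WT), 52 (exposure in KO) and 53 (interaction). DESeq2 gave 128, 113, 195, 233 and 272 in hippocampus in that order. It gave 17, 213, 3013 and 241 in vermis for exposure in WT and KO, genotype in ethanol and the interaction, and 1 and 18 for the tissue tests in WT and KO. Without a sex term the interactions gave 23 and 41, and exposure in WT vermis 0. The replicate label as a block gave 0, 7 and 6 in vermis for exposure in WT, in KO and the interaction. The labels did not pair libraries across groups, since the correlation of libraries with the same label ran from -0.344 to 0.385 in hippocampus and -0.359 to 0.223 in vermis, and 5 of 16 libraries in each tissue were closest to their own label. Sex by group cells gave 14 and 7 for the interactions. Fits of only the groups compared gave 0 (exposure in KO), 2 (genotype in saline) and 8 (genotype in ethanol) in hippocampus. They gave 5 (exposure in WT), 1 (exposure in KO) and 693 (genotype in ethanol) in vermis. With sex in place of mouse, the tissue test in KO gave 0.

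The length offset gave 29 for exposure in KO and 2 for genotype in saline in hippocampus, and 642 for genotype in saline and 48 for the interaction in vermis. Protein-coding genes only gave 29 and 31 for exposure in KO in hippocampus and vermis. The choroid plexus covariate gave 67 for genotype in ethanol hippocampus and turned the direction of the test of the choroid plexus list in exposure in KO (median 0.076 in place of 1.61). The brainstem covariate gave 0 and 7 for exposure in WT and KO vermis and reversed Hoxb5 in the latter (-0.57). Leaving out saline WT M3 and ethanol KO F1 in hippocampus gave 3 (exposure in KO), 24 (genotype in ethanol) and 13 (interaction). Leaving out saline WT F1 and ethanol KO F1 in vermis gave 0 (exposure in WT) and 12 (exposure in KO). The Acss2 term of exposure in WT vermis, -0.020, was 0.011 in that fit and ran from -0.053 to 0.022 with each library left out, with 0.013 without ethanol WT F3 and 0.022 without saline WT F1. It passed in none of them. Over genes of at least 10 CPM the correlation was -0.012 in hippocampus and -0.344 in vermis. The share of genotype calls near Acss2 was 5.00% within 5 Mb and 5.28% within 20 Mb in saline vermis, above the 4.91% and 4.90% elsewhere rather than below.

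With each library left out, hippocampal counts ran from 0 to 21 (exposure in WT), 0 to 19 (exposure in KO), 1 to 92 (genotype in saline), 6 to 45 (genotype in ethanol) and 0 to 24 (interaction). Vermis counts ran from 0 to 2, 2 to 616, 760 to 1246, 973 to 5092 and 3 to 168 in that order. The tissue test ran from 0 to 2 in KO and stayed at 0 in WT. Exposure by sex ran from 0 to 4 in WT hippocampus and 0 to 21 in WT vermis and stayed at 0 in KO. The correlations ran from 0.040 to 0.248 in hippocampus and -0.246 to 0.085 in vermis, which was 0.030 without ethanol WT M1. The Acss2 difference ran from -2.24 to -2.19 and from -1.96 to -1.83.

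Of the values of genes that the rule named, 354 of 427 kept their direction and side of the threshold with DESeq2 (72 newly passed, 1 lost its call), 423 of 427 with RLE scaling, 277 of 343 with only the groups compared (60 lost their call), and 5993 of 6824 with a library left out (768 lost it, 53 gained it, 10 reversed). Of 82 list values 68 lost their call with an estimated correlation and 51 with fry. With a library left out 36 of 1312 lost it, 3 gained it and 2 reversed. In exposure in WT hippocampus values reversed without ethanol WT F3, with ranges over the libraries left out, for Otx2 (-0.28 to 1.16), Sostdc1 (-0.17 to 0.87), Lbp (-0.21 to 0.89), Kcne2 (-0.25 to 1.75), Dynlrb2 (-0.19 to 1.37), Cfap126 (-0.046 to 0.95), Cfap144 (-0.22 to 0.45), Sntn (-0.48 to 1.14) and the ependyma and motile cilia list (-0.42 to 0.85). The choroid plexus median there ran from -0.41 (without ethanol WT F3) to 1.16. Its camera direction turned without saline WT F3 instead, where the median stayed positive (0.053). The choroid plexus covariate reversed both lists there (-0.12 for ependyma and motile cilia, -0.025 for the choroid plexus) and Kl in genotype in saline hippocampus (0.073). The glucocorticoid list of exposure in KO hippocampus (-0.39 to -0.15), of exposure in WT vermis (0.31 to 0.42) and of the interactions (-0.54 to -0.42 in hippocampus, -0.74 to -0.56 in vermis) passed in each of 24 alternatives. So did the ribosomal list in vermis in saline (0.48 to 0.75) and ethanol (0.56 to 0.89). Depth limits the genes near 1 CPM most in ethanol KO vermis F3.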

Other observations

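The lists described in this part were chosen after the values were seen, from lists written before the data were examined. In the hippocampus, genes that write, erase and read histone acetylation were positive in 32 of 38 after ethanol in WT (median log2 0.08), with 0 genes passing over all genes or adjusted over the list alone (adjusted p = 0.000135, and adjusted p = 0.261 with an estimated correlation), a median of 0.046 with an offset for transcript length. For genotype among ethanol-exposed mice 28 of 38 were negative (median -0.083), again with 0 passing (adjusted p = 0.000264, and adjusted p = 0.316 with an estimated correlation). In the interaction 28 of 38 were negative (median -0.075), and the acetyltransferase Crebbp (-0.38 ± 0.10 SE) and the deacetylase Hdac7 (-0.39 ± 0.11) passed adjusted over the list alone (adjusted p = 0.000159, and adjusted p = 0.288 with an estimated correlation). The median of the histone acetylation writers erasers and readers there was -0.12 without saline WT M3 or ethanol KO F1 and -0.13 without saline KO M3. In ethanol-exposed KO vermis Sirt3, a mitochondrial deacetylase, rose (0.44 ± 0.086) while Sin3a (-0.31 ± 0.070), Brd2 (-0.23 ± 0.063) and Brd1 (-0.25 ± 0.070) fell against WT (list median -0.067, adjusted p = 0.0045, and adjusted p = 0.619 with an estimated correlation). Brd2, Brd1 and the list (-0.041) lost their calls with an offset for transcript length, and the list median was -0.11 without ethanol WT F1 and -0.14 without ethanol KO F3.

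Genes of ethanol and aldehyde metabolism were positive in 14 of 15 after ethanol in KO hippocampus (median log2 0.16, adjusted p = 0.000129, and adjusted p = 0.503 with an estimated correlation) and in 15 of 15 for genotype among ethanol-exposed mice (0.15, adjusted p = 0.000191, and adjusted p = 0.465 with an estimated correlation), with 0 genes passing over all genes or adjusted over the list alone. In ethanol-exposed KO vermis 4 rose over all genes and 7 adjusted over the list alone, among them the antioxidant enzymes Sod1 (0.58 ± 0.089 SE) and Gpx1 (0.82 ± 0.13) (adjusted p = 0.00118, and adjusted p = 0.506 with an estimated correlation). Sod1 lost its call with an offset for transcript length (0.24), while Gpx1 kept its call (0.62). Of 26 genes of the heat shock and unfolded protein response 6 rose there over all genes and 10 adjusted over the list alone, such as Manf (0.70 ± 0.15), Pdia6 (0.56 ± 0.12) and Hsp90b1 (0.38 ± 0.094) (adjusted p = 2.59e-05, and adjusted p = 0.619 with an estimated correlation). The median of the heat shock and unfolded protein response was 0.29, and 0.16 without ethanol KO M3. In the hippocampal interaction, the DNA methylation machinery had 1 gene with a negative term over all genes, Tet3 (-0.66 ± 0.10), and 3 adjusted over the list alone with Dnmt3a (-0.38 ± 0.10) and Tet2 (-0.41 ± 0.13) (adjusted p = 0.0119, and adjusted p = 0.451 with an estimated correlation), a list call lost without saline WT M3 (adjusted p = 0.054). The median of the DNA methylation machinery was -0.14, and -0.031 without saline WT M3, -0.087 without ethanol KO F1 and -0.056 with an offset for transcript length, and the call was lost with both libraries left out (-0.037).

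Between the tissues of the same mouse the median correlation of library values was 0.031, against -0.004 between different mice, across genes, which are not independent replicates.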
